A study of Vitis labrusca and Vitis cinerea and Vitis acerifolia with 56 samples.

How the data were processed

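Total RNA of grape berries was sequenced on Illumina instruments in 56 libraries labelled Vitis labrusca (24 libraries), Vitis cinerea (22 libraries) and Vitis acerifolia (10 libraries). Clusters had grown in sunlight or inside boxes of 40 by 25 by 25 cm covered with aluminium foil. Per the labels, the authors aligned the reads with TopHat2 2.0.14 and estimated expression with Cufflinks 2.2.1. The deposited table gives FPKM (fragments mapped, scaled by transcript length and by the total of the library) for 29971 genes with grapevine gene model identifiers and no gene descriptions. The genome build is not given in the sources used here. FPKM values hold no read counts, so the depth of each library is unknown and no counting interval is given.

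The libraries fell into 35 groups by species, stage and light treatment, of which 21 held 2 libraries and 14 held 1. Stage and treatment were taken from the titles and descriptions. The descriptions of the V. labrusca libraries name V. cinerea, and these libraries were used as their titles and organism entries state. At veraison, the libraries of replicate 2 labelled V. labrusca in sunlight and V. labrusca boxed carry a stage entry of 2 weeks after veraison that conflicts with their titles, and they were used as veraison. The light status at harvest was coded as sunlight, boxed (still in the box) or re-exposed (box removed at an earlier stage). The comparisons, tests, gene lists and the first set of alternatives were chosen before the data were examined.

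Expression was analysed as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 libraries of a fit were tested with limma 3.58.1 in R 4.3.3, with the empirical Bayes trend and a Benjamini-Hochberg adjusted p under 0.05. The mature comparisons and the stage comparisons came from 1 fit with a coefficient per group over the 46 V. labrusca and V. cinerea libraries (20333 genes, 21 residual degrees of freedom). The boxed and re-exposed comparisons over stages came from 1 fit of light status within species, blocked by species and stage, over 51 libraries of all 3 species (20252 genes, 34 residual degrees of freedom). A group with 1 library was thus assumed to vary like the others. The V. acerifolia library 2 weeks after veraison had no other library of its stage and entered no comparison. Differences between species were tested as differences of the fitted contrasts.

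Of 19 gene lists fixed in advance, 9 could be formed from grape gene identifiers recalled from the literature without looking them up: anthocyanin branch (12 genes), early flavonoid steps (21 genes), general phenylpropanoid steps (9 genes), stilbene synthases (49 genes), proanthocyanidin branch (5 genes), flavonol synthesis (3 genes), light signalling (2 genes), abscisic acid (1 gene) and sugar cleavage (2 genes). The other 10 needed gene descriptions and could not be formed: lignin, light harvesting, carbon fixation, ethylene, auxin, cell wall, defence, heat shock, seed and cell division. The assignment of names to identifiers was not checked against an annotation here. Members of the MYBA, chalcone synthase, F3'5'H and stilbene synthase families have near copies, so the assignment of reads among them is uncertain. Named genes were every tested anthocyanin gene and, for each other list, at most 4 genes with the smallest p. Other genes could be named only with a description, which left none. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. No list whose median, mean and test differed in sign was called.

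The labels give 1 anthocyanin concentration per library. The mean concentrations of boxed and sunlight berries over veraison and maturity together were compared. Labels were permuted within each stage in an exact two-sided test. The correlation of each anthocyanin gene with the concentration was tested by 100000 two-sided permutations, adjusted over the 12 genes of a species, with a smallest possible p of 1e-05. In V. cinerea these correlations used the libraries with a concentration under 3, because the 5 above it stood apart, and V. acerifolia was given none because its libraries form separate clusters. A position in ripening was computed per library as its projection on the line from the pre-veraison libraries (0) to the mature re-exposed ones (1). It used the genes outside the lists that differed by a log2 change of at least 2 between these ends (2046 genes in V. labrusca, 2904 in V. cinerea), without the doubted libraries in either end.

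Sample identity was checked with species-private genes, defined on the 25 libraries harvested up to veraison: the lowest library of 1 species lay at least 1 log2 unit above the highest of the others. This gave 22 genes for V. labrusca, 13 for V. cinerea and 271 for V. acerifolia. Each library was scored by the share of each set above the midpoint of that gap, with a library's own values left out of the definition. No list of markers for other tissues could be formed.

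Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling of the libraries within species, quantile normalization, a replicate block, a fit of 1 species alone, the libraries with conflicting stage labels left out, and each library left out in turn. After the data were seen, fits without 9 libraries of doubted species, fits without 3 sparse libraries and a comparison of boxed with sunlight berries at pre-veraison were added. Up to 100 other splits of the libraries within stages were fitted per comparison over stages. The fits were tested on simulated data with 200 changed genes, all with a mean log2(FPKM + 1) above 2. The recovered shares therefore do not hold for genes with lower values. In the mature V. labrusca comparison, 20.6%, 56.1% and 90.9% of genes with a log2 change of 1, 2 and 4 were recovered, and 10.5% of the calls were false. In the boxed V. labrusca comparison the recovered shares were 38.2%, 81.8% and 98.5%, with 8.23% of calls false. A simulated lowered list of 12 genes was called in 6 of 6 comparisons. The simulated noise was independent between genes, so this does not test the lists where genes vary together. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The co-expression network named as an aim of the study was not analysed here.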

Results

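Berry transcriptomes were measured by RNA sequencing in 3 grape species grown with and without sunlight on the cluster. The study describes V. acerifolia and V. cinerea as accumulating anthocyanins without sunlight and V. labrusca as depending on it. Berries were taken at 5 stages: young berry, pre-veraison (2 weeks before veraison, the onset of ripening), veraison, 2 weeks after veraison, and maturity. Light was excluded until pre-veraison, until veraison or throughout, beside berries kept in sunlight. V. labrusca gave 8 sunlight, 6 boxed and 8 re-exposed libraries, V. cinerea gave 7, 5 and 8, and V. acerifolia gave 3, 3 and 4; V. labrusca and V. cinerea also gave 2 young berry libraries each. V. labrusca and V. cinerea had 1 or 2 libraries per condition, and V. acerifolia had 1, so that its values have no replicates. Total FPKM per library ranged from 764972 to 1882693, and read depth was unknown. The 10 most abundant genes took from 6.87% to 42.5% of a library's FPKM. In 3 V. labrusca libraries (replicate 1 of the young berries, of the veraison sunlight berries and of the berries excluded until pre-veraison and taken 2 weeks after veraison) low values were sparse. There the lowest 1% of positive values ended at 1.07 to 1.18 FPKM, against 0.0659 to 0.214 in the other libraries. These 3 libraries held 11880 to 14509 genes above 0, the others 16683 to 19989.

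In V. labrusca, mature berries excluded from sunlight throughout had an anthocyanin concentration of 0 in both libraries, against 1.83 ± 0.788 (SD, n = 2) in sunlight. The labels give no unit for it. At veraison the boxed V. labrusca berries were also at 0 and the sunlight berries at 0.465 ± 0.363 (SD, n = 2). Mature V. labrusca berries uncovered at pre-veraison reached 2.14 ± 0.233 (SD, n = 2), and those uncovered at veraison 1.66 ± 0.145 (SD, n = 2). V. cinerea berries excluded throughout still held 1.53 ± 0.628 (SD, n = 2), below the 6.09 ± 1.24 (SD, n = 2) of sunlight berries. In the libraries labelled mature V. acerifolia the concentration was 4.12 excluded throughout and 3.62 in sunlight. The boxed minus sunlight difference, in means pooled over veraison and maturity, was -1.15 in V. labrusca. Its exact two-sided p, permuted within stage, was 0.0556 for 4 against 4 libraries, the smallest this design allows. Without the library labelled mature sunlight replicate 2 it was -0.735. The difference in V. cinerea was -2.05 (exact p = 0.222, 3 against 4 libraries, smallest possible 0.0556), and in V. acerifolia it was 0.249 (exact p = 1, 2 against 2 libraries, smallest possible 0.5). The V. cinerea difference was -0.754 (exact p = 0.778) without the library labelled mature sunlight replicate 1 and -1.34 without mature sunlight replicate 2. It was -3.05 and -3.07 without veraison sunlight replicate 1 and 2, and -4.57 without the veraison boxed library, which left maturity alone. That of V. acerifolia was 0 without either mature library and 0.497 without either veraison library. In the main V. cinerea comparison, and without a mature sunlight library, boxed and sunlight berries held unequal shares of mature libraries. Those differences and their p therefore also reflect the mix of stages. The value 1.276 occurs for V. labrusca replicate 1 in sunlight both 2 weeks after veraison and at maturity. Likewise, 2.39 occurs both for mature sunlight replicate 2 and for replicate 2 excluded until pre-veraison and taken 2 weeks after veraison.

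**Figure D1:**
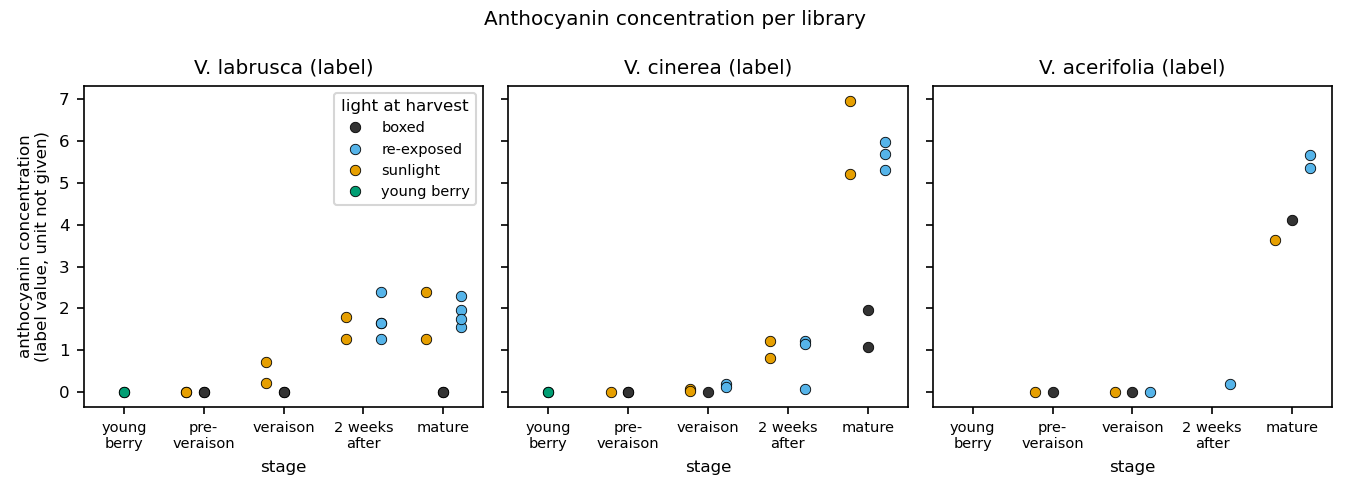
Anthocyanin concentration from the labels (unit not given) for each library by stage, with 1 panel per species and colour for the light status at harvest. Boxed V. labrusca berries lie at 0 at every stage, while the libraries labelled mature boxed V. cinerea and V. acerifolia lie between 1.085 and 4.12.

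Species-private genes, which up to veraison stood at least 1 log2 unit higher in every library of 1 species than in any of the others, followed the labels in all 25 libraries of these stages. In these libraries the set of the labelled species was seen at 65.6% or more and another set at no more than 13.3%. Of the 31 libraries taken later, 22 matched their label and 9 did not. V. cinerea genes were seen at 76.9% to 100% in the mature libraries labelled V. acerifolia in sunlight, excluded until pre-veraison and excluded until veraison. The library labelled V. cinerea, mature, sunlight replicate 1 showed V. labrusca genes at 77.3%. Those labelled V. labrusca, mature, sunlight replicate 2 and V. labrusca, mature, excluded until pre-veraison replicate 2 showed V. cinerea genes at 46.2% and 69.2%. In these 6 libraries, genes of the labelled species stood at 7.69% or less, against 21.4% to 90.9% in the 22 matching ones. Another 3 libraries, taken 2 weeks after veraison and labelled V. cinerea (both replicates excluded until pre-veraison and replicate 2 excluded until veraison), showed V. acerifolia genes at 19.9% to 22.9%, close to the 21.4% of the library labelled V. acerifolia, mature, excluded throughout. Their V. cinerea genes stood at 7.69% or less, against 23.1% or more in the matching late V. cinerea libraries. The library labelled V. acerifolia, mature, excluded throughout is counted as matching by its private genes. With these left out it correlated best with V. cinerea (r = 0.896, against 0.833 with V. acerifolia). No matching V. acerifolia library it was compared with was mature, so stage alone could lower that r. It correlated at 0.957 to 0.968 with the 3 libraries labelled V. cinerea. The other 21 matching ones correlated best with their own species. The species of that library was thus left undecided, and no library from mature V. acerifolia is free of doubt. The comparisons use the labels as given. Each main count is also given without these 9 libraries, a choice made after seeing the data.

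**Figure D2:**
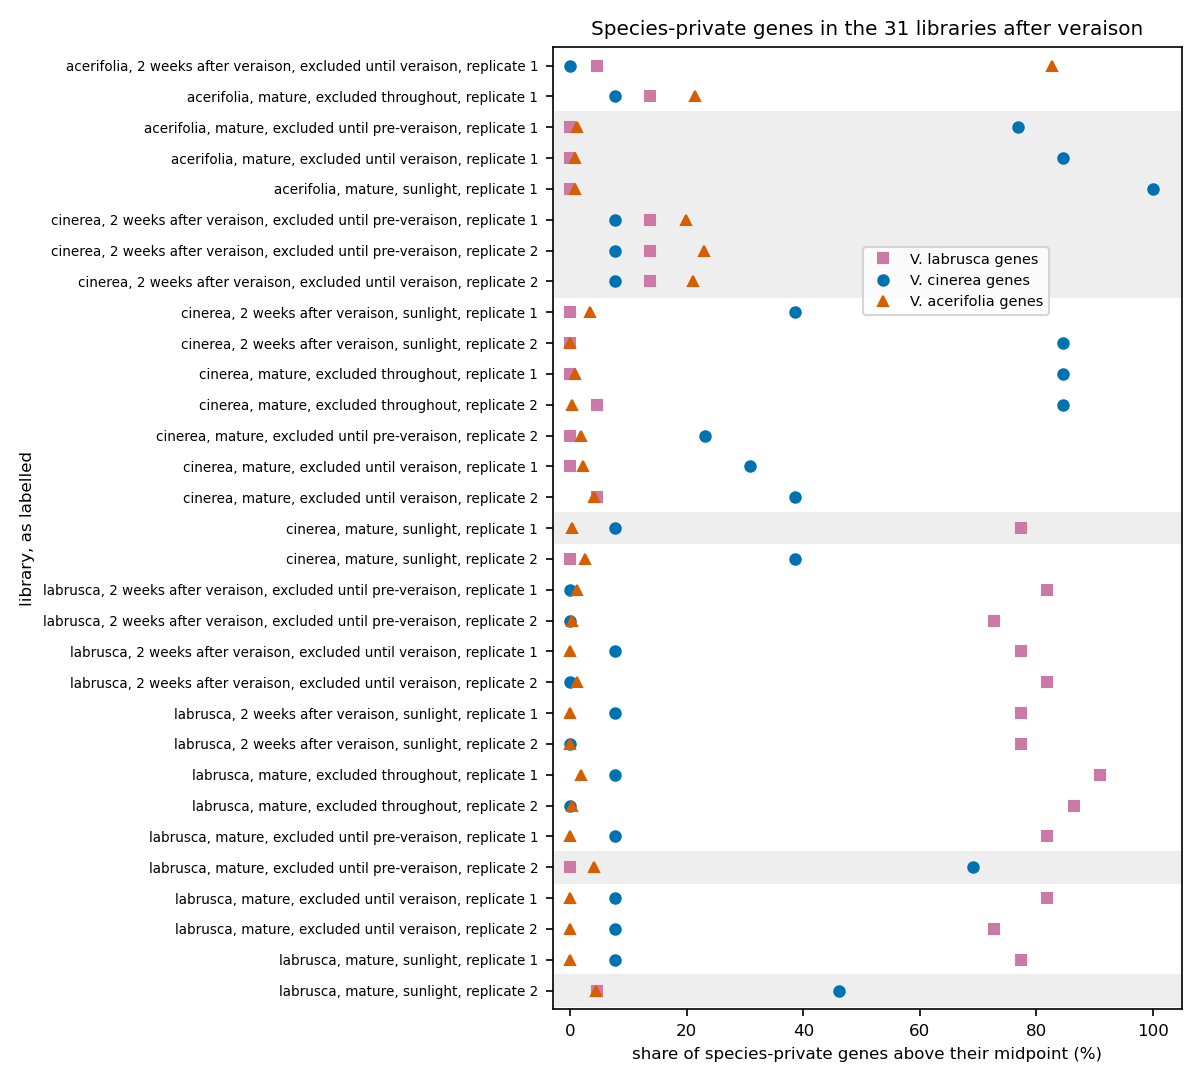
Share of species-private genes above their midpoint (%) in each of the 31 libraries taken after veraison, with 1 marker per species' gene set and the 9 libraries that do not match their label shaded. Matching V. labrusca libraries show 72.7% to 90.9% of the V. labrusca genes, and the shaded V. labrusca libraries show at most 4.55%.

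Ripening in sunlight raised the anthocyanin pathway in V. labrusca. Of its 12 anthocyanin genes, 11 rose from pre-veraison to maturity and 0 fell (12 rose when adjusted over the list alone). Among them were GST4 (VIT_04s0079g00690), which carries anthocyanins to the vacuole, with a log2 change of 7.41 (adjusted p = 3.34e-05), and UFGT (VIT_16s0039g02230), which glucosylates anthocyanidins, with 4.92 (adjusted p = 0.00228). MYBA1 (VIT_02s0033g00410), an activator of UFGT, rose by 3.11. Of the 11, AOMT (VIT_01s0010g03510) and AM1 (VIT_16s0050g00930) lost the call without the 9 libraries, without the library labelled mature sunlight replicate 2 and without either pre-veraison library. DFR (VIT_18s0001g12800) lost it without mature sunlight replicate 1 or either pre-veraison library, and 3AT (VIT_03s0017g00870) without mature sunlight replicate 1 or pre-veraison sunlight replicate 2. Early flavonoid genes rose in 8 of 19 cases (9 adjusted over the list alone), led by the chalcone synthase CHS3 (VIT_05s0136g00260) with 5.28 (adjusted p = 7.7e-05). Phenylpropanoid genes rose in 5 of 9 cases (5 adjusted over the list alone), with the phenylalanine ammonia-lyase PAL (VIT_13s0019g04460) at 5.42 (adjusted p = 1.33e-06). The vacuolar invertase GIN1 (VIT_16s0022g00670) fell by 7.10 (adjusted p = 0.000418). The anthocyanin, early flavonoid and phenylpropanoid lists each rose with an estimated correlation (adjusted p = 0.00769), whereas the stilbene synthases, called higher with the preset correlation, had an adjusted p = 0.786 with an estimated correlation. In limma 0 of the 40 passed, with 1 at an unadjusted p under 0.05. In all, 995 genes rose and 2909 fell; after median-ratio scaling, which moved the median gene by 0.149, 1309 rose and 2234 fell. The total of 3904 became 2407 without the 9 libraries, 1942 and 2098 without pre-veraison sunlight replicate 1 and 2, and 2066 without mature sunlight replicate 2.

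In V. cinerea, ripening in sunlight was tested against the only pre-veraison sunlight library, which could not be left out in turn. UFGT rose by 4.003 (adjusted p = 0.0368), the regulator MYBA2 (VIT_02s0033g00390) by 4.13 (adjusted p = 0.00113) and the anthocyanin transporter gene AM3 (VIT_16s0050g00910) by 2.14 (adjusted p = 0.0249), giving 3 of 12 anthocyanin genes (3 adjusted over the list alone). The call for UFGT was lost without either mature sunlight library, without the 9 libraries, with a pseudocount of 0.1, with no filter, with the replicate block and in a fit of V. cinerea alone, and that for AM3 without replicate 2 and in the latter fit. PAL (VIT_13s0019g04460) rose by 3.31 (adjusted p = 0.00215), the only 1 of 9 phenylpropanoid genes, and 0 of 19 early flavonoid genes passed in limma, with 2 at an unadjusted p under 0.05. In the proanthocyanidin branch, ANR (VIT_00s0361g00040), which makes flavan-3-ols, fell by 4.84 (adjusted p = 0.00453), and LAR2 (VIT_17s0000g04150) fell by 2.43 (adjusted p = 0.0457, lost without either mature sunlight library, without the 9 libraries, with a pseudocount of 0.1, with no filter and after scaling). GIN1 fell by 6.98 (adjusted p = 0.00337). HY5 (VIT_04s0008g05210), a bZIP factor of light signalling, fell by 4.24 (adjusted p = 0.0207), a call lost without mature sunlight replicate 2. The anthocyanin, early flavonoid and phenylpropanoid lists were higher at the preset correlation but had an adjusted p = 0.362 each with an estimated correlation, and the stilbene synthases an adjusted p = 0.527. Over all genes, 795 rose and 2978 fell (1200 and 2356 after scaling, which moved the median gene by 0.174), and without the 9 libraries 3449 passed in place of 3773. The difference in ripening between the species was not tested.

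From the young berry to pre-veraison, 4 of 9 phenylpropanoid genes of V. labrusca fell and 1 rose (6 fell and 1 rose adjusted over the list alone). The fallen genes included the coumarate ligase 4CL (VIT_11s0052g01090), which fell by 4.76 (adjusted p = 8.96e-05), and the cinnamate hydroxylase C4H (VIT_06s0004g08150), which fell by 2.76; the risen 4CL (VIT_16s0050g00390) lost its call without either pre-veraison library or young berry replicate 2. As a list they had an adjusted p = 0.269 with an estimated correlation. MYBA1 and MYBA2 rose by 2.37 and 2.38, the 2 called of 12 anthocyanin genes; without young berry replicate 1, either pre-veraison library or the sparse libraries both calls were lost. In all, 572 genes rose and 855 fell. The total of 1427 was 1655 without the 9 libraries, 833 and 620 without pre-veraison sunlight replicate 1 and 2, 2249 without young berry replicate 2, and 935 with a pseudocount of 0.1. In V. cinerea, again with 1 pre-veraison sunlight library that could not be left out, 4CL (VIT_16s0050g00390) rose by 2.92 (adjusted p = 0.00152), MYBA1 by 2.67 (adjusted p = 0.0189) and LAR2 by 2.68 (adjusted p = 0.0373), and no list passed. The latter pair of calls was lost without either young berry library. Here 1028 genes rose and 1524 fell, a total of 2552 that was 3010 without the 9 libraries and 1321 without young berry replicate 2.

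In V. labrusca, berries still boxed at harvest had lower transcripts of genes between phenylalanine and the anthocyanins than sunlight berries of the same stage. The regulators MYBA1, MYBA2 and MYBA3 (VIT_02s0033g00450) fell by 2.28, 2.24 and 2.63, and LDOX (VIT_02s0025g04720), which makes anthocyanidins, fell by 2.38 (SE 0.55, adjusted p = 0.00708). At veraison MYBA1 stood at 11.5 ± 5.92 FPKM boxed and 90.7 ± 0.0201 in sunlight (SD, n = 2 each). The anthocyanin list had 6 of 12 genes lower and 0 higher (9 lower adjusted over the list alone). UFGT, at 40.4 ± 28.5 FPKM boxed against 415 ± 165 in sunlight at veraison (SD, n = 2 each), had a log2 difference of -2.30 and did not pass (adjusted p = 0.0592). Early flavonoid genes were lower in 9 of 19 cases and higher in 0 (12 lower adjusted over the list alone). CHS2 (VIT_14s0068g00920) and CHS3 fell by 2.40 and 2.62, and the flavanone hydroxylases F3H1 (VIT_04s0023g03370) and F3H2 (VIT_18s0001g14310) fell by 2.49 and 1.91. Of 9 phenylpropanoid genes 4 fell (5 adjusted over the list alone), among them PAL (VIT_13s0019g04460) by 3.34 (SE 0.50, adjusted p = 0.000177) and C4H by 1.78. With an estimated correlation the adjusted p was 0.000448 for the early flavonoid list and 0.0166 each for the anthocyanin and phenylpropanoid lists. LDOX, MYBA1, CHS3 and this PAL were below the sunlight mean of their stage in 6 of 6 boxed libraries.

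The light-signalling genes HY5 and its homologue HYH (VIT_05s0020g01090) were also lower in boxed V. labrusca berries, with log2 differences of -1.999 (adjusted p = 0.0353) and -2.19 (adjusted p = 0.00366), in 6 of 6 libraries each. The flavonol synthase FLS1 (VIT_18s0001g03470) fell by 3.18 (adjusted p = 0.0166), 1 of 3 flavonol genes, and MYBPA1 (VIT_15s0046g00170), an activator of proanthocyanidin genes, fell by 1.80 (adjusted p = 0.0397), 1 of 5 proanthocyanidin genes. GIN1 rose by 2.99 (adjusted p = 0.0382), a call lost after median-ratio scaling. NCED1 (VIT_19s0093g00550), an enzyme of abscisic acid synthesis, did not pass, with a log2 difference of 0.24. Of the stilbene synthases 0 of 41 passed in limma, with 0 at an unadjusted p under 0.05, and the list, higher at the preset correlation, had an adjusted p = 0.63 with an estimated correlation. Of the 19 named genes with a call, 12 kept it whichever library was left out and 19 kept it without the 9 libraries. HY5 kept it only without mature sunlight replicate 2, pre-veraison boxed replicate 1, pre-veraison sunlight replicate 2 or veraison sunlight replicate 2, MYBPA1 only without either pre-veraison sunlight library, pre-veraison boxed replicate 2 or veraison sunlight replicate 2, and GIN1 only without any 1 of the 4 pre-veraison libraries. MYBA3, FLS1, the transporter gene AM1 (VIT_16s0050g00930) and 4CL (VIT_16s0039g02040) lost it without either mature boxed library. MYBA3, AM1 and 4CL also lost it without veraison boxed replicate 2, FLS1 and AM1 without veraison sunlight replicate 1, AM1 and 4CL without mature sunlight replicate 2, and AM1 without veraison boxed replicate 1. HY5, MYBPA1, GIN1 and AM1 lost it without the sparse libraries, HY5, MYBPA1 and FLS1 in a fit of V. labrusca alone, and MYBA3 with a pseudocount of 0.1. Without the libraries with conflicting stage labels HY5, MYBPA1, GIN1, 4CL, MYBA2, MYBA3, AM1 and AM3 lost it, so that of the 6 called anthocyanin genes LDOX and MYBA1 kept their calls. Over all genes 996 were higher and 281 lower (482 and 359 after scaling). The total of 1277 was 1445 without the 9 libraries, 826 without the sparse ones and 638 without those with conflicting stage labels; it was 680 and 482 without mature boxed replicate 1 and 2, 755 and 601 without veraison boxed replicate 1 and 2, and 682 without veraison sunlight replicate 1.

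**Figure D3:**
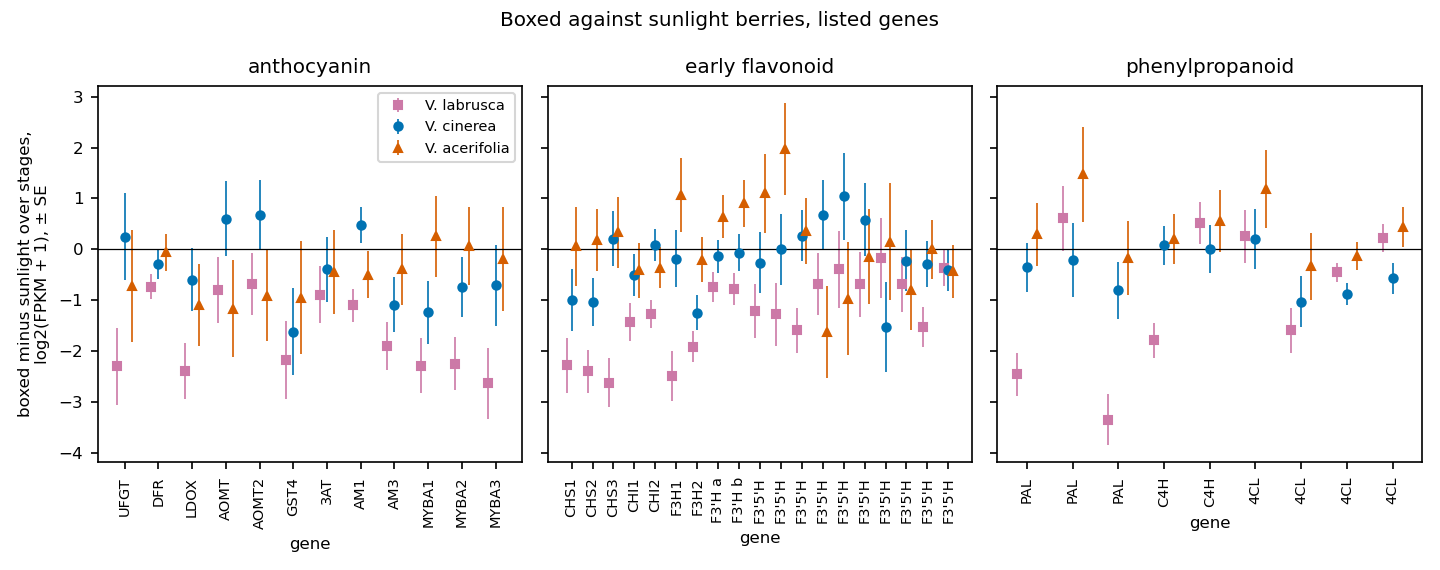
Boxed minus sunlight difference over stages in log2(FPKM + 1), with bars for ± 1 SE, for each anthocyanin, early flavonoid and phenylpropanoid gene, with colour for the species. V. labrusca values reach -3.34 for PAL (VIT_13s0019g04460), and 19 genes of these lists passed the threshold in V. labrusca, 1 in V. cinerea and 0 in V. acerifolia.

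At maturity, V. labrusca berries that had never seen sunlight had lower transcripts of early pathway genes than sunlight berries. PAL (VIT_13s0019g04460) stood at 10.5 ± 3.99 FPKM against 273 ± 19.3 in sunlight (SD, n = 2 each), a log2 difference of -4.62 (SE 0.59, adjusted p = 0.000143). CHS2 fell by 3.19 (adjusted p = 0.00463) and F3H2 by 2.79 (adjusted p = 0.00493). Early flavonoid genes were lower in 7 of 19 cases and higher in 0 (9 lower adjusted over the list alone), and phenylpropanoid genes in 3 of 9 (4 adjusted over the list alone). Of the anthocyanin genes 3 of 12 were lower (6 adjusted over the list alone), with log2 differences of -2.70 for LDOX (adjusted p = 0.0294), -2.27 for MYBA1 (adjusted p = 0.033) and -1.85 for AM3 (adjusted p = 0.0499). UFGT stood at 34.0 ± 1.23 against 129 ± 3.03 FPKM (SD, n = 2 each) and did not pass. GIN1 rose by 4.82 (adjusted p = 0.0335). With an estimated correlation the early flavonoid list remained lower (adjusted p = 0.0113), while the anthocyanin and phenylpropanoid lists each had an adjusted p = 0.0551 and the stilbene synthases, higher at the preset correlation, an adjusted p = 0.408. In limma, 0 of 40 stilbene synthases passed (12 at an unadjusted p under 0.05), as did 0 of 5 proanthocyanidin, 0 of 3 flavonol and 0 of 2 light-signalling genes (1 of each unadjusted). The higher stilbene synthase values came from 1 library: their sum was 491.8 FPKM in replicate 1 excluded throughout and 2.743 in replicate 2. In the libraries labelled sunlight it was 14.55 and 53.04. Among 11 called named genes, PAL (VIT_13s0019g04460) and CHS2 kept the call whichever library was left out and without the 9 libraries. The other 9 lost it without the 9 libraries, without replicate 2 excluded throughout and without the library labelled sunlight replicate 2, and LDOX, MYBA1, AM3, GIN1, an F3'H gene (VIT_17s0000g07200) and PAL (VIT_06s0004g02620) also without replicate 1 excluded throughout. AM3 and GIN1 lost it without sunlight replicate 1 too, and AM3 without the sparse libraries, with a pseudocount of 0.1 and with no filter.

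The mature V. labrusca comparison called 898 genes, of which 660 were higher (402 higher and 308 lower after scaling), and without the 9 libraries it called 402. The total moved to 377 and 416 without replicate 1 and 2 excluded throughout, to 1939 and 165 without sunlight replicate 1 and 2, and to 1368 without the sparse libraries. On a scale of ripening from 0 at pre-veraison to 1 in mature re-exposed berries, both libraries excluded throughout lay at 0.523 and 0.447. The sunlight library that matches its label lay at 0.974, and the library labelled sunlight replicate 2 at 0.814. Boxed V. labrusca berries at veraison lay at 0.457 and 0.376, against 0.689 and 0.684 in sunlight.

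**Figure D4:**
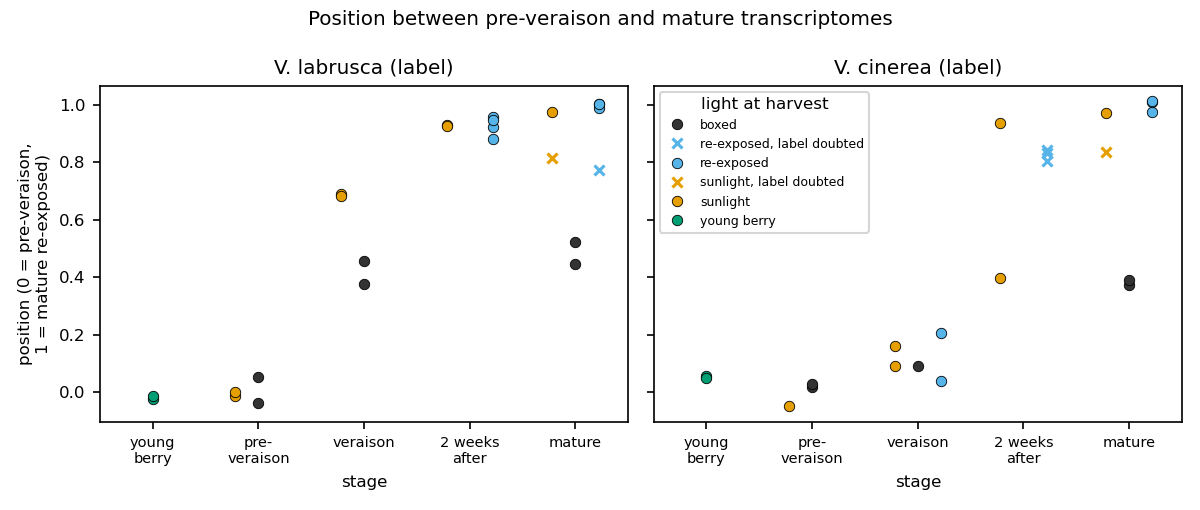
Position of each V. labrusca and V. cinerea library between the pre-veraison (0) and the mature re-exposed (1) transcriptomes, by stage and light status, with crosses for libraries that do not match their label. Mature berries excluded throughout lie at 0.447 and 0.523 in V. labrusca and at 0.375 and 0.392 in V. cinerea.

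Mature V. cinerea berries excluded from sunlight throughout had higher transcripts of part of the anthocyanin genes than sunlight berries, with a lower labelled anthocyanin concentration. UFGT stood at 1134 ± 20.97 FPKM against 66.9 ± 0.445 (SD, n = 2 each), a log2 difference of 4.06 (SE 1.09, adjusted p = 0.0182). The anthocyanin methyltransferase AOMT2 (VIT_01s0010g03490) rose by 4.15 (adjusted p = 0.00115), LDOX by 2.44 (adjusted p = 0.0302) and MYBA1 by 1.97 (adjusted p = 0.0407). In all 5 of 12 anthocyanin genes rose and 0 fell (8 rose adjusted over the list alone), and all 5 were above the sunlight mean in 2 of 2 libraries. With an estimated correlation the list had an adjusted p = 0.241. Early flavonoid genes rose in 2 of 19 cases (5 adjusted over the list alone): a chalcone isomerase locus (VIT_13s0067g02870) by 1.60 and an F3'5'H gene (VIT_06s0009g02860) by 3.27. Of the phenylpropanoid genes 0 of 9 passed in limma, with 1 at an unadjusted p under 0.05. Of the stilbene synthases, a list that was lower at the preset correlation (adjusted p = 0.727 with an estimated correlation), 0 of 40 passed, with 0 unadjusted. Both invertases rose, GIN1 by 4.57 (adjusted p = 0.0266) and GIN2 (VIT_02s0154g00090) by 2.32 (adjusted p = 0.00913). Of 9 called named genes, AOMT2 was the only 1 that kept its call whichever library was left out, and each of the others lost it without either library excluded throughout. LDOX also lost it without sunlight replicate 2. Without the library labelled sunlight replicate 1, which shows V. labrusca genes, 7 lost it: UFGT, MYBA1, the methyltransferase AOMT (VIT_01s0010g03510), the chalcone isomerase locus, the F3'5'H gene, GIN1 and GIN2. Without the 9 libraries 3 (LDOX, AOMT2 and GIN2) kept it. UFGT, AOMT and MYBA1 lost it with a pseudocount of 0.1, UFGT, LDOX, MYBA1 and GIN1 in a fit of V. cinerea alone, and MYBA1 after scaling and with no filter. UFGT lost its call on leaving out any 1 of the 4 libraries, while its log2 difference stayed between 4.04 and 4.08.

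This V. cinerea comparison called 2035 genes, 1594 higher and 441 lower. After scaling, which moved the median gene by -0.143, 1204 were higher and 633 lower. The total was 1332 without the 9 libraries, 605 and 623 without replicate 1 and 2 excluded throughout, and 918 without the library labelled sunlight replicate 1. The berries excluded throughout lay at 0.375 and 0.392 in ripening, against 0.973 for the sunlight library that matches its label and 0.836 for the library labelled sunlight replicate 1. Replicates of 1 stage could lie far apart on this scale: both V. cinerea sunlight libraries 2 weeks after veraison, which match their label, lay at 0.937 and 0.397.

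**Figure D5:**
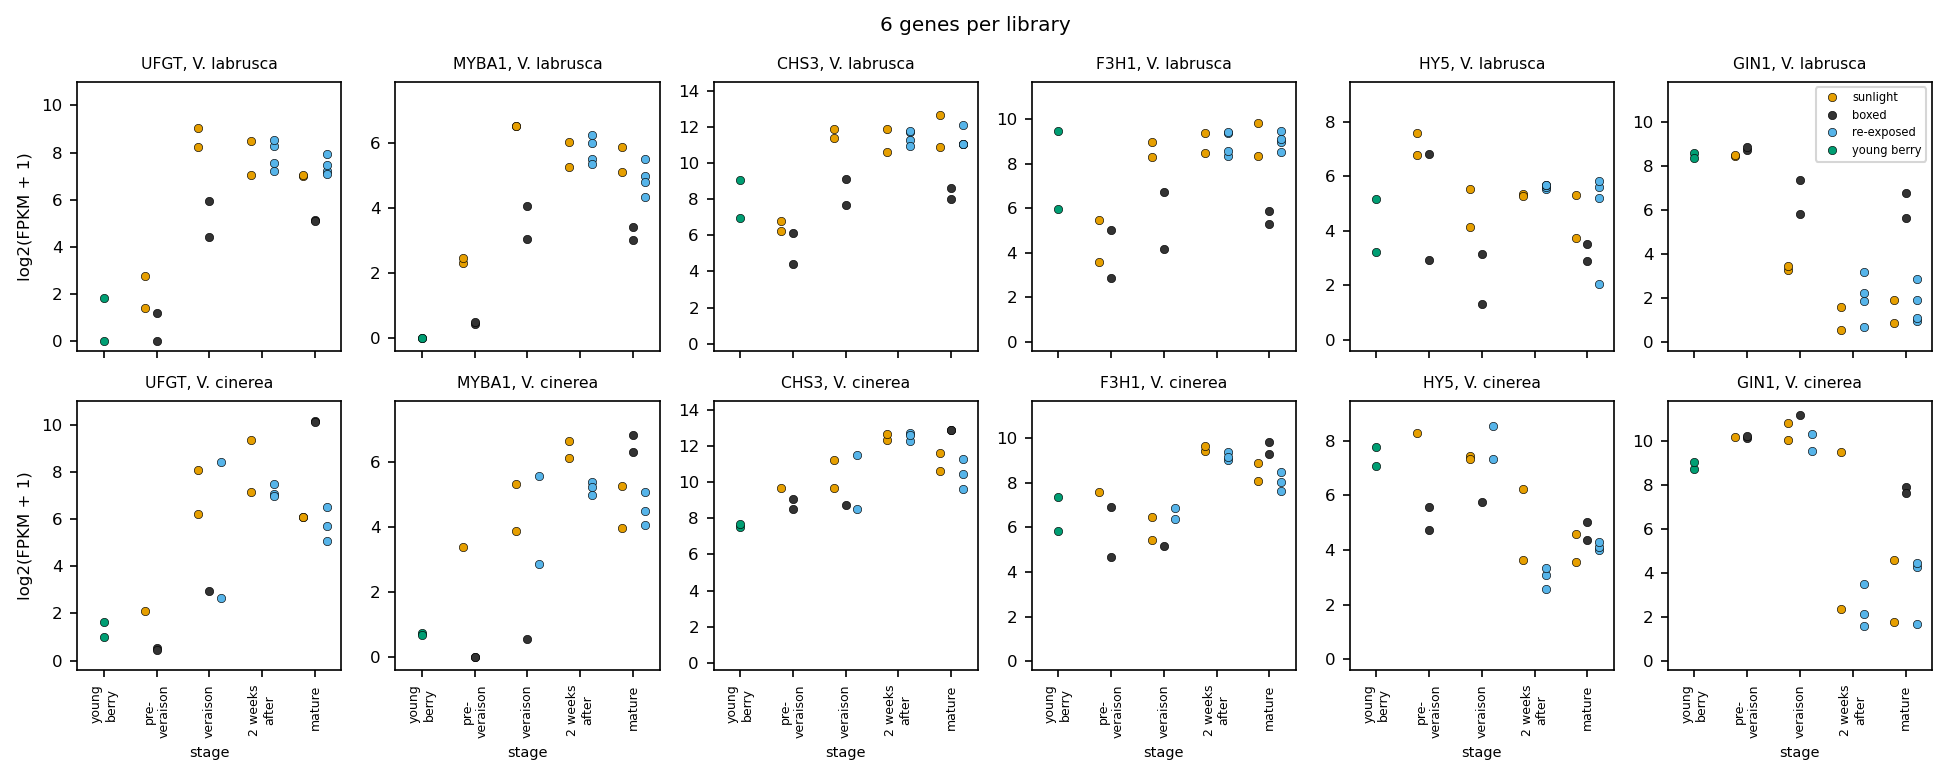
Expression of UFGT, MYBA1, CHS3, F3H1, HY5 and GIN1 as log2(FPKM + 1) in each V. labrusca and V. cinerea library by stage, with colour for the light status at harvest. UFGT averages 34.0 FPKM in mature V. labrusca and 1134 FPKM in mature V. cinerea berries excluded throughout.

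With the labels as given, the response of mature berries to lifelong exclusion differed between the species in the pigment pathway. In each species, however, a mature sunlight library showed the private genes of the other species. If these are mislabelled, the difference partly or wholly compares the species themselves rather than their responses to light. The V. labrusca minus V. cinerea difference was negative for 4 of 12 anthocyanin genes and positive for 0 (10 negative adjusted over the list alone): LDOX at -5.14 (adjusted p = 0.0133), AOMT2 at -5.09 (adjusted p = 0.0163), MYBA1 at -4.24 (adjusted p = 0.0163) and AM3 at -3.46 (adjusted p = 0.0255). Early flavonoid genes followed with 2 of 19 (12 adjusted over the list alone), CHS3 at -5.21 (adjusted p = 0.0261) and the chalcone isomerase locus VIT_13s0067g02870 at -3.35 (adjusted p = 0.00486). Of 9 phenylpropanoid genes 2 differed (4 adjusted over the list alone), PAL (VIT_13s0019g04460) at -5.48 (adjusted p = 0.00299) and C4H at -3.89 (adjusted p = 0.0163). The anthocyanin and early flavonoid lists differed with an estimated correlation (adjusted p = 0.0123 and 0.0146), and the phenylpropanoid and stilbene synthase lists did not (adjusted p = 0.212 each). Without the 9 libraries these adjusted p became 0.0517 and 0.0525, and of the 8 called genes LDOX and PAL kept their call. PAL was also the only 1 of the 8 that kept it whichever library was left out, and each of the others lost it without V. labrusca sunlight replicate 2 and, except the chalcone isomerase locus, without V. cinerea replicate 1 excluded throughout. In all 95 genes differed upward and 167 downward, a total of 262 that was 105 without the 9 libraries, 461 without the sparse ones and 140 with a pseudocount of 0.1. It was 31 and 52 without V. cinerea replicate 1 and 2 excluded throughout, 60 and 680 without V. cinerea sunlight replicate 1 and 2, 110 without V. labrusca replicate 1 excluded throughout, and 1147 and 15 without V. labrusca sunlight replicate 1 and 2. Across 20333 genes, which are not independent replicates, the mature responses of the species correlated at r = 0.261; 191 genes were higher and 48 lower in both, against 51.7 and 5.16 by chance, and 15 moved in opposite directions. That r was 0.278 without the 9 libraries, with 54 higher and 15 lower in both against 11.4 and 3.20 by chance, and 6 in opposite directions.

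Over all stages, boxed V. cinerea berries showed few called differences from sunlight berries. This fit gave each species a single light difference over its stages, so differences of opposite sign between stages would offset each other. The V. cinerea anthocyanin list had a median log2 difference of -1.46 at pre-veraison, while its called anthocyanin genes were higher at maturity. Few calls here thus do not show a weak response at each stage. A 4CL gene (VIT_16s0050g00390) was the only listed gene to pass, at -0.88 (SE 0.21, adjusted p = 0.0488), and it lost its call on leaving out any 1 of the 10 libraries, with a pseudocount of 0.1, with the replicate block and in a fit of V. cinerea alone. In limma, 0 of 12 anthocyanin and 0 of 19 early flavonoid genes passed, with 0 and 1 adjusted over the list alone and 0 and 2 at an unadjusted p under 0.05. The anthocyanin, early flavonoid and phenylpropanoid lists were lower at the preset correlation and had an adjusted p = 0.571, 0.398 and 0.251 with an estimated correlation. In all 55 genes were higher and 18 lower (35 and 24 after scaling), and 3173 had an unadjusted p under 0.05. The total of 73 was 123 without the 9 libraries, 185 without the sparse ones, 130 with no filter, 23 with a pseudocount of 0.1 and 2 in a fit of V. cinerea alone. It was 17 and 9 without mature boxed replicate 1 and 2, 110 without the pre-veraison sunlight library, 14 without mature sunlight replicate 2 and 749 without the only veraison boxed library (replicate 2).

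V. acerifolia berries still boxed had lower values of the light-signalling genes at pre-veraison and veraison, in 1 library per condition. HY5 stood at 118 and 66.1 FPKM in boxed berries of these stages, against 489 and 340 in sunlight. At maturity it stood at 1.01 and 70.8 in the libraries labelled excluded throughout and sunlight, both of doubted species. Its log2 difference of -3.18 had an adjusted p = 0.0618 and that of HYH, -2.26, an adjusted p = 0.0965, so that 0 of 2 passed over all genes and 2 passed adjusted over the list alone. A stilbene synthase (VIT_16s0100g00840) rose by 2.85 (SE 0.73, adjusted p = 0.0487), 1 of 41 (5 adjusted over the list alone); the list, higher at the preset correlation, had an adjusted p = 0.455 with an estimated correlation. That call was kept only without the veraison boxed library among the 6 left out in turn. It was lost without the 9 libraries, without the sparse ones, with a pseudocount of 0.1, after median-ratio scaling, with the replicate block and in a fit of V. acerifolia alone. Of the list, 18 of 41 genes had an unadjusted p under 0.05 and 3 of 38 without the 9 libraries, where its adjusted p was 0.88 with an estimated correlation. In limma, 0 of 12 anthocyanin, 0 of 19 early flavonoid and 0 of 9 phenylpropanoid genes passed, with 0, 1 and 0 at an unadjusted p under 0.05, and UFGT stood at 139 and 661 FPKM in the libraries labelled mature boxed and mature sunlight. In all 53 genes were higher and 118 lower, and 2506 had an unadjusted p under 0.05. The total of 171 became 313 without the 9 libraries, which leaves pre-veraison and veraison only, 606 with no filter, 61 with a pseudocount of 0.1 and 0 in a fit of V. acerifolia alone with 2024 unadjusted. It was 313 without the mature boxed library, 101 without the pre-veraison boxed library and 103 without the pre-veraison sunlight library.

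The boxed responses compared here are averages over the stages, in which V. cinerea differences of opposite sign would offset each other. Between species, the early flavonoid list was more strongly lowered in boxed V. labrusca than in boxed V. cinerea berries (adjusted p = 0.0258 with an estimated correlation), with 0 of 19 genes passing in limma, 6 at an unadjusted p under 0.05 and 4 adjusted over the list alone. Without the 9 libraries that adjusted p was 0.156. The anthocyanin list had an adjusted p = 0.239, and limma called 0 genes, with 1646 at an unadjusted p under 0.05, and 0 without the 9 libraries, with 2231 unadjusted. The count was 9 without V. cinerea veraison boxed replicate 2, 3 without V. cinerea mature boxed replicate 1, 9 and 3 without V. labrusca pre-veraison boxed replicate 1 and 2, 6 and 4 without V. labrusca pre-veraison sunlight replicate 1 and 2, and 1 without V. labrusca mature boxed replicate 1, without V. labrusca veraison boxed replicate 1 or without the libraries with conflicting stage labels. Against V. acerifolia, F3H1 differed by -3.55 (adjusted p = 0.0438), 1 of 19 early flavonoid genes (10 adjusted over the list alone), a call lost without 12 of the 18 libraries in turn, without the 9 libraries, the sparse ones or those with conflicting stage labels, with a pseudocount of 0.1 and after quantile normalization. The early flavonoid and phenylpropanoid lists differed with an estimated correlation (adjusted p = 0.00917 and 0.0258), with 0.0787 and 0.243 without the 9 libraries. The anthocyanin and stilbene synthase lists did not (adjusted p = 0.263 and 0.365). In all 70 genes differed upward and 44 downward (44 and 37 after scaling, which moved the median gene by -0.146). The total of 114 was 170 without the 9 libraries, 43 without those with conflicting stage labels, 32 with a pseudocount of 0.1, 221 with no filter and 47 after quantile normalization. It was 178 without V. acerifolia mature boxed, 73 and 60 without V. labrusca mature boxed replicate 1 and 2, 188 and 194 without V. labrusca pre-veraison boxed replicate 1 and 2, 183 without V. labrusca pre-veraison sunlight replicate 1, 72 without V. labrusca veraison sunlight replicate 1 and 68 without V. labrusca veraison boxed replicate 2.

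After re-exposure, no listed gene differed from sunlight berries of the same stage in any of the 3 species over all genes tested. In V. labrusca, limma called 0 genes, with 278 at an unadjusted p under 0.05, and 0 without the 9 libraries; the median log2 difference was 0.13 for the anthocyanin and 0.11 for the early flavonoid list. No V. labrusca list passed (lowest adjusted p = 0.0662), although 3 passed at the preset correlation without the 9 libraries, with adjusted p from 0.185 to 0.604 with an estimated correlation. In V. cinerea, 30 of 41 stilbene synthases, which make resveratrol, were higher adjusted over the list alone, with 0 over all genes in limma and 33 at an unadjusted p under 0.05. Without the 9 libraries 0 of 38 were higher by either count, with 0 at an unadjusted p under 0.05. The 3 doubted libraries labelled V. cinerea 2 weeks after veraison had stilbene synthase sums of 420 to 1798 FPKM, against 204.5 and 3.75 in the sunlight libraries of that stage and at most 334 in the other V. cinerea libraries. As a list the stilbene synthases had an adjusted p = 2.09e-26 at the preset correlation and 0.142 with an estimated correlation, and without the 9 libraries 1.74e-08 and 0.418. The V. cinerea anthocyanin and early flavonoid lists, lower at the preset correlation, had an adjusted p = 0.25 and 0.343 with an estimated correlation. V. acerifolia had higher early flavonoid and proanthocyanidin lists (adjusted p = 0.0344 each with an estimated correlation), both lost without the 9 libraries, while its anthocyanin and phenylpropanoid lists had an adjusted p = 0.312 and 0.253. Limma called 4 genes in V. cinerea, with 2318 at an unadjusted p under 0.05. They were VIT_11s0052g01320, VIT_04s0008g05390 and VIT_10s0003g01650, with log2 differences of 1.81, 1.49 and 2.65, and VIT_11s0016g03210 with -0.73 (adjusted p from 0.023 to 0.026), named after their values were seen. That count was 1 without the 9 libraries, 7 with a pseudocount of 0.1 and 0 in a fit of V. cinerea alone; it was 0 without replicate 1 excluded until pre-veraison and taken 2 weeks after veraison, or without either sunlight library of that stage. It was 1 without replicate 2 excluded until veraison of that stage, 12 and 10 without mature sunlight replicate 1 and 2, and 43 without veraison replicate 2 excluded until pre-veraison. In V. acerifolia 8 genes were called, 2 higher and 6 lower (3 and 5 after scaling), with 114 without the 9 libraries, 5 with a pseudocount of 0.1, 109 with no filter and 0 in a fit of V. acerifolia alone. Leaving out a library gave 25 and 21 without mature berries excluded until pre-veraison and until veraison, 81 without mature sunlight and 15 without veraison berries excluded until pre-veraison.

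Boxed and sunlight berries were also compared at pre-veraison alone, a comparison added after the data were seen. V. cinerea had 1 sunlight library there, which could not be left out, and its spread was assumed from the other groups. In boxed V. cinerea berries 2 of 12 anthocyanin genes were lower. MYBA1 had a log2 difference of -3.38 (SE 0.75, adjusted p = 0.0294), at 0 FPKM in both libraries against 9.40 in 1 sunlight library, and AM3 had -2.93 (SE 0.66, adjusted p = 0.0353). In V. labrusca, MYBA1, HY5 and HYH had log2 differences of -1.91, -2.29 and -2.27 and did not pass. The V. labrusca anthocyanin and early flavonoid lists, lower at the preset correlation, had an adjusted p = 0.0573 each with an estimated correlation. The V. cinerea anthocyanin, early flavonoid and phenylpropanoid lists had median log2 differences of -1.46, -0.973 and -0.998. They too were lower at the preset correlation, and none passed with an estimated correlation. In V. labrusca 4 genes were higher and 6 lower, and in V. cinerea 25 were higher and 96 lower.

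Among V. labrusca libraries from veraison on, 4 of 12 anthocyanin genes correlated with the labelled concentration by Pearson's r. AM1 (VIT_16s0050g00930) had r = 0.727 (permutation adjusted p = 0.00396) and Spearman's rho = 0.714 (permutation adjusted p = 0.0164) over 18 libraries, and LDOX had r = 0.709 (permutation adjusted p = 0.0066) with rho = 0.399. GST4 and AM3 had r = 0.621 and 0.665, each with a permutation adjusted p of 0.00741. Without the 2 libraries farthest from the median concentration 0 of 12 passed (lowest permutation adjusted p = 0.0828), with r = 0.646 for AM1, 0.600 for LDOX, 0.540 for AM3 and 0.510 for GST4 over 16 libraries. Centred on the stage means, 6 genes passed, with r from 0.145 to 0.770 over the 12, and 6 by Spearman's rho. By r 9 passed without the 9 libraries and by rho 0, against 4 and 1 with them. In V. cinerea, r ranged from 0.523 to 0.759 over 12 libraries and 0 genes passed (lowest permutation adjusted p = 0.0519), while 3 passed by r and 10 by rho without the 9 libraries. The limit on the concentration left out every mature V. cinerea library in sunlight or re-exposed. The only mature ones kept were those excluded throughout, so these r and counts depend on that choice. Without the 2 farthest libraries r ranged from 0.471 to 0.728. Centred on the stage means over 17 libraries, with the mature ones left out above included, r ranged from -0.674 to -0.161 and 0 genes passed. The sign of r in V. cinerea thus changed with the libraries and the centring used.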

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

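The tests of library identity (mislabelling, mixing and ripening loss in the 6 libraries, and mislabelling in the 3 libraries and in the V. cinerea anthocyanin pattern) were chosen only after the result was seen, and the comparison at pre-veraison was added after the data were seen, with its bound written before its own result.

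In 6 libraries taken after veraison, the species-private genes are those of another species than the label. A mixture with RNA of another species is argued against, because genes of the labelled species stood at 7.69% or less in these libraries. In the 22 matching ones they stood at 21.4% or more. Without the library labelled V. acerifolia excluded throughout, which is in doubt, this was 23.1% or more. A loss of species-private expression during ripening is argued against in V. labrusca, where matching late libraries exceeded the mismatching ones by 68.15 percentage points or more. Both gaps are partly built in, because the libraries were sorted into matching and mismatching by these same shares. A mislabelled sample remains a candidate explanation: with the private genes left out, 6 of the 6 correlated best with label-matching libraries of the species their private genes point to. For the 3 labelled V. acerifolia, which correlated with V. cinerea at 0.950 to 0.970, that test cannot decide. The only label-matching mature V. acerifolia library is itself in doubt, so stage alone could lower their r with V. acerifolia. A swap between V. cinerea mature sunlight replicate 1 and V. labrusca mature sunlight replicate 2 is open. Their labelled concentrations of 6.97 and 2.39 lie nearer those of their labelled groups (5.22 and 1.276), which a swap of the RNA alone would leave in place. For the 3 libraries labelled V. cinerea 2 weeks after veraison, a mislabelled sample and a correct label cannot be told apart. Their V. cinerea genes stood at 7.69% or less, against 23.1% or more in the matching late V. cinerea libraries. Among label-matching libraries they correlated best with the one labelled V. acerifolia excluded throughout (0.957 to 0.968), itself in doubt. With that left out they correlated best with V. cinerea, but at r as low as 0.877. This was below the lowest r within a species of the others, 0.901. No label-matching mature V. acerifolia library was then left to compare with. No biological explanation was tested.

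In mature V. cinerea berries excluded from sunlight throughout, 5 of 12 anthocyanin genes were called higher, at a lower labelled concentration. The anthocyanin list did not pass with an estimated correlation. A mislabelled sample as the cause and a true difference cannot be told apart: without the 9 libraries the median log2 difference of the 12 anthocyanin genes was 2.093, but that leaves 1 sunlight library, and of the 5 called genes LDOX and AOMT2 kept their calls. Ripening behind the sunlight berries is a candidate explanation, since the berries excluded throughout lay at least 0.581 lower on the ripening scale than the only mature sunlight library that matches its label. That lag rests on 1 sunlight library, and the label-matching sunlight replicates 2 weeks after veraison themselves lay at 0.937 and 0.397. The scale leaves out the anthocyanin genes, so it does not show which way a delay would move them. UFGT was higher at maturity than at pre-veraison in V. cinerea sunlight berries, so a delay alone need not raise it. The light treatment itself, which the design names, stays open and was not separated from that delay.

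Flavonoid gene transcripts were lower in boxed V. labrusca berries. Ripening behind the sunlight berries is a candidate explanation, since mature berries excluded throughout lay at least 0.451 lower on the ripening scale than the only mature sunlight library that matches its label. At pre-veraison the early flavonoid list was lower at p = 0.01335 with an estimated correlation (0.0573 adjusted over the lists), but there a delay and an effect of light cannot be told apart, because the scale places young berries (-0.022 and -0.011) within the pre-veraison libraries that define its 0 end (-0.038 to 0.052). A direct effect of sunlight, which the design names, stays open as a hypothesis and was not tested.

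With the labels as given, the responses of V. labrusca and V. cinerea to exclusion throughout differed at maturity in 262 genes by the test of the difference itself. That count fell without the 9 libraries and without the library labelled V. labrusca sunlight replicate 2, which shows V. cinerea genes. A V. cinerea sunlight library likewise showed V. labrusca genes. If these are mislabelled, the difference partly or wholly compares the species themselves rather than their responses to light. The difference (V. labrusca minus V. cinerea) was -5.14 for LDOX, -5.09 for AOMT2, -3.46 for AM3, -4.24 for MYBA1, -5.21 for CHS3, -3.35 for the chalcone isomerase locus VIT_13s0067g02870, -5.48 for PAL (VIT_13s0019g04460) and -3.89 for C4H (VIT_06s0004g08150); without the 9 libraries LDOX and PAL kept their calls and the other 6 lost them. With an estimated correlation it had an adjusted p of 0.01233 for the anthocyanin list and 0.01462 for the early flavonoid list, which became 0.0517 and 0.0525 without the 9 libraries. Over the boxed stages the early flavonoid list differed between these species with an adjusted p of 0.02583, and 0.156 without the 9 libraries. Against V. acerifolia the boxed response of V. labrusca differed in 114 genes, with -3.55 for F3H1, a call lost without the 9 libraries. There the early flavonoid and phenylpropanoid lists differed with an adjusted p of 0.009172 and 0.02579, and 0.0787 and 0.243 without the 9 libraries.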

How the results depend on the processing

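The fits without the 9 libraries and without the 3 sparse libraries were chosen after the data were seen; the other alternatives were planned. Of the counts of genes called, 143 stayed within 1.5 times the reported count and 93 moved. The 540 values of named genes gave 8092 alternatives on the same side of the threshold, 261 weaker and 128 stronger, with 0 reversed. Only 88 of the 540 values were called in the main fits, so most of the 8092 are values that stayed uncalled. The 261 weaker ones are lost calls, 177 of them on leaving out 1 library. With the replicate block all 15 counts stayed within that factor, for example 1014 for mature V. labrusca. The replicate numbers were not treated as pairs, because the labels do not say that a number marks a shared plant, day or batch. Differences between replicate 1 and 2 correlated above 0.1 in 6 of 66 pairs of groups in V. labrusca (r from -0.224 to 0.742, median 0.0222). In V. cinerea they did so in 15 of 36 (-0.114 to 0.430, median 0.0701) and fell below -0.1 in 2. A shared effect of the number in V. cinerea is thus not excluded. For every moved count the cause was not tested. A pseudocount of 0.1 gave 140 for the mature species difference, 23 for boxed V. cinerea, 61 for boxed V. acerifolia, 32 for V. labrusca minus V. acerifolia, 7 and 5 for re-exposed V. cinerea and V. acerifolia, and 935 for V. labrusca from young berry to pre-veraison. No filter gave 130 for boxed V. cinerea, 606 and 109 for boxed and re-exposed V. acerifolia, and 221 for V. labrusca minus V. acerifolia. Median-ratio scaling gave 841 for boxed V. labrusca, and quantile normalization 47 for V. labrusca minus V. acerifolia. Fits of 1 species alone gave 2 and 0 for boxed V. cinerea and V. acerifolia and 0 for both when re-exposed. Without the libraries with conflicting stage labels boxed V. labrusca gave 638, its difference from V. cinerea 1 and from V. acerifolia 43. Without the 9 libraries the counts were 402, 1332 and 105 at maturity (V. labrusca, V. cinerea, difference), 123, 313 and 170 boxed (V. cinerea, V. acerifolia, V. labrusca minus V. acerifolia), 1 and 114 re-exposed (V. cinerea, V. acerifolia), and 2407 for V. labrusca ripening. Without the sparse libraries they were 1368 for mature V. labrusca, 461 for the mature difference, 826 for boxed V. labrusca and 185 for boxed V. cinerea. Leaving out 1 library in turn, counts ranged at maturity from 165 to 1939 in V. labrusca, 605 to 1695 in V. cinerea and 15 to 1147 for the difference. Boxed, they ranged from 482 to 1693 in V. labrusca, 9 to 749 in V. cinerea, 101 to 313 in V. acerifolia, 0 to 9 for V. labrusca minus V. cinerea and 60 to 194 for V. labrusca minus V. acerifolia. Re-exposed, they ranged from 0 to 0 in V. labrusca, 0 to 43 in V. cinerea and 11 to 81 in V. acerifolia. Ripening in sunlight gave 1942 to 4304 in V. labrusca and 2908 to 3305 in V. cinerea, and young berry to pre-veraison 620 to 2249 and 1321 to 1802. Of 6 lists tested per comparison, an estimated correlation left 1 called in mature V. labrusca, 0 in mature V. cinerea, 2 for the mature difference, 0 in boxed V. cinerea and V. acerifolia, 1 and 2 for the boxed differences from V. cinerea and V. acerifolia, 0 and 2 in re-exposed V. cinerea and V. acerifolia, 0 in ripening V. cinerea and 0 in V. labrusca before veraison. With fry the numbers were 1 in mature V. cinerea, 0 in boxed V. cinerea and V. acerifolia, 1 and 2 for the boxed differences, and 0 in re-exposed V. cinerea, re-exposed V. acerifolia and ripening V. cinerea. Without the 9 libraries 3 lists were called in re-exposed V. labrusca, 0 in re-exposed V. acerifolia and 2 in ripening V. cinerea. Anthocyanin genes correlated with the concentration numbered 0 in V. labrusca without the 2 farthest libraries and, without the 9 libraries, 9 in V. labrusca and 3 in V. cinerea. Read depth is unknown, so its effect on low values was not assessed.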

Other observations

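The V. acerifolia library excluded until veraison and taken 2 weeks after veraison, which enters no comparison, had a labelled concentration of 0.193. UFGT stood there at 371 FPKM, MYBA1 at 45.3, LDOX at 1248, CHS3 at 2822 and PAL (VIT_13s0019g04460) at 55.1. GIN1 stood at 570 FPKM and HY5 at 101. In the libraries labelled mature V. acerifolia, excluded throughout and sunlight, which are both of doubted species, GIN1 stood at 2.40 and 585 FPKM.

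Other splits of the same libraries within their stages were fitted for the comparisons over stages; those without the 9 libraries were chosen after the data were seen. Chance can be excluded for boxed V. labrusca, where the real split called 1277 genes and the highest of the others, among 100 splits, 662; without the 9 libraries these were 1445 and 974. The splits cannot decide the difference between V. labrusca and V. acerifolia (114 genes, highest other 123, with 2 of 100 splits as large). They shuffled light in both species at once, so a difference in V. labrusca alone could give that share. For re-exposed V. cinerea 4 of 100 splits, the real one included, called at least the 4 genes of the real one (highest other 78). That share is below 0.05, but the count was 0 without any 1 of 3 libraries and 1 without the 9, so chance is not excluded there. It cannot be excluded for boxed V. cinerea, with 73 genes against a highest other of 684 in 54 splits, nor without the 9 libraries, with 123 against 1026 in 27 splits (3 as large). The splits decide nothing for the difference between V. labrusca and V. cinerea over the boxed stages (0 genes, highest other 265) or for re-exposed V. labrusca (0 genes, highest other 453), because all 100 splits call at least 0 genes. For boxed V. acerifolia, with 171 genes and a highest other of 113, the 4 splits are too few for a share under 0.05. Other splits called far more genes than the real one in boxed and re-exposed V. cinerea, in re-exposed V. labrusca and for V. labrusca minus V. cinerea. The cause was not tested.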
